A study of Mus musculus with 4 samples.

How the data were processed

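RNA of purified migrasomes and of cytosol of mouse origin was profiled by RNA sequencing in 2 libraries per group, 4 in all, grouped by the sample titles. The submitters' processing notes name cutadapt, Trimmomatic, FastQC, STAR, HTSeq and DESeq, without versions, and the build GRCm38. The deposited values are a signal per gene, gene counts that the authors divided by 1 size factor per library, per the labels' list of tools and the values themselves. The gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here, so overlapping and antisense genes, pseudogenes and near-identical copies are uncertain. The table holds 49568 gene symbols.

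Every value was a whole multiple of the smallest value above 0 in its library, within a tolerance of 0.001, so whole reads were recovered for 100% of the values. Recovered totals were 7529136 and 8608369 reads in cytosol and 5228713 and 5171092 in migrasome, and 1 read is worth 0.776, 0.686, 1.41 and 1.32 in cytosol replicates 1 and 2 and migrasome replicates 1 and 2. A gene with no read is below the value of 3 reads, which is 2.33, 2.06, 4.24 and 3.95 in the same order. That floor covers counting error only, since reads without molecular identifiers are not independent molecules. Over genes with at least 20 summed reads, chi-square over its degrees of freedom was 27.9 between the migrasome libraries and 17.6 between the cytosol libraries, so neither pair is 1 library deposited again.

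Values were taken as log2(value + 1), which understates the change of low genes. Genes with a value of at least 10 in at least 2 of the 4 libraries were tested with limma 3.58.1 (eBayes with a trend) in R 4.3.3, without a replicate block, with Benjamini-Hochberg adjustment and a threshold of 0.05. A count model was not the main test because the deposited values are normalised. edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads as alternatives. Gene lists with at least 5 tested members, 27 of them, were tested with camera at its preset correlation of 0.01 and adjusted over the lists, and 10 passed as higher and 8 as lower. With an estimated correlation, which the 2 residual degrees of freedom make imprecise, 0 lists passed and the smallest adjusted p was 0.40. The fry test, which asks whether a list's genes move one way without comparing them with other genes, passed 4 lists (migrasome proteins, mitochondrially encoded mRNAs, protrusion-localised mRNAs and neural markers).

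The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 largest positive and 12 largest negative differences among genes past the threshold with a mean of at least 50 in the higher group and no overlap of the groups, leaving out predicted and unnamed models (77 of the higher and 81 of the lower calls). It also took up to 4 of the most abundant tested members of each list and the 10 most abundant genes of each group. The text names part of these, and some results the rule covers are not reported here. Trak2, Myc, Cyr61, mt-Rnr1, Snhg20, Rny3, Vcl, Sec61b and Sec61g fall outside the rule and were chosen after their values were seen. The same holds for Slc7a5, Slc38a2, Slc25a5, Snora73a, Scarna2 and Rnu12, and for the untested mt-Nd3, mt-Nd4l, mt-Atp6 and mt-Atp8. Positions, exon lengths, GC content and coding sequences came from the GENCODE M21 annotation of GRCm38, in which 47313 symbols were found, 458 more by a synonym, and 1797 were not, Snhg7 among those without a position.

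The test was tried on simulated data with the real means. It called 34 of 100 genes changed by 2 and 88 of 100 changed by 4, with 7 false calls among 10839 genes, and 0 to 1 calls in 5 runs without change. The simulation drew genes independently, with the same dispersion in both groups. It therefore leaves out shifts that many genes of a library share, and the larger spread of the migrasome libraries. False calls in the real data may be more frequent. Alternatives changed the pseudocount, the filter, the scaling, the variance model, the count tool, the replicate block, each left-out library, a fold minimum, and corrections for exon length and GC content. Thinning the reads to equal depth was added after the data were seen. Figures were drawn with matplotlib 3.10.9.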

Results

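Migrasomes are large vesicles that form on the retraction fibres that a migrating cell leaves behind it. The series profiled, by RNA sequencing of mouse samples, the RNA of purified migrasomes (2 libraries) and of cytosol (2 libraries). The type of cell that the material came from is not given in the sources used here. The libraries held 7529136 and 8608369 reads assigned to genes in cytosol replicates 1 and 2, and 5228713 and 5171092 in migrasome replicates 1 and 2. At least 1 read was seen for 16098 and 16082 genes in the cytosol libraries and for 14848 and 15171 genes in the migrasome libraries. Values below are the deposited normalised read counts, with the mean ± SD of n = 2 libraries per group, and differences are given as migrasome minus cytosol on the log2(value + 1) scale with a standard error (SE). The labels do not say that the libraries came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

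The question set by the series title and design is which mRNAs migrasomes carry. Of 10860 genes tested with limma, 2862 passed an adjusted p (Benjamini-Hochberg) of 0.05, of which 943 were higher in migrasome and 1919 lower. At least a doubling was seen for 300 of the genes that were higher, and at least a halving for 1558 of those that were lower. These sizes are point estimates, and a limma test against a 2-fold change passed only 29 genes higher and 73 lower. Both migrasome libraries lay on one side of both cytosol libraries for 69.5% of the tested genes, where 33.3% is the chance for a single gene. Genes of a library do not vary independently, so the distance between these shares is not a test. A single gene compared by an exact permutation test of 2 libraries against 2 cannot reach below p = 0.33, so the calls rest on the spread shared across genes. Without cytosol replicate 1 or 2 the count fell to 1433 or 1414, and without migrasome replicate 2 it was 4885. Scaling every library to the same total left 322 genes higher and 2522 lower, against 1194 and 1403 with quantile normalization.

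The largest increase was that of Nmt2, an N-myristoyltransferase that attaches a fatty acid to proteins, on chromosome 2 from 3284212 to 3328877 on the plus strand (GRCm38, GENCODE M21 annotation, as are all positions given). Its value was 24575 ± 13422 (SD, n = 2) in migrasome and 1321 ± 115 in cytosol, a log2 difference of 4.10 ± 0.34 (SE, limma adjusted p = 0.00035). Fgd3, an exchange factor for the GTPase Cdc42 on chromosome 13 from 49261554 to 49320311 (minus strand), stood at 3796 ± 69.6 in migrasome and 287 ± 34.2 in cytosol, with a log2 difference of 3.72 ± 0.20. Cdc42bpg, a kinase bound by Cdc42, was higher by 3.12 ± 0.27 and the exchange factor Net1 by 2.90 ± 0.20. The other genes with the largest increases were Mir1983 (3.50), the synaptic protein gene Cplx2 (3.30), Rab13 (3.03), the 7SL RNA gene Rn7s1 (2.94), Nol3 (2.93), Trim12c (2.91), Trp53inp2 (2.89) and mt-Nd5 (2.81). All 12 passed the limma test, with both migrasome libraries above both cytosol libraries. Mir1983 was low in cytosol, at 3.56 ± 1.75, so its difference is imprecise (SE 0.53).

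The largest decreases were those of Snhg7, a host of small nucleolar RNAs (-3.53 ± 0.39), and Terc, the RNA component of telomerase (-3.45 ± 0.28), both past the limma test. Terc, on chromosome 3 from 96414437 to 96414859 (minus strand), fell from 812 ± 183 in cytosol to 74.4 ± 23.2 in migrasome. Rn7sk, the nuclear 7SK RNA on chromosome 9 from 78175303 to 78175633 (minus strand), fell from 70394 ± 1653 to 9690 ± 4304, a log2 difference of -2.94 ± 0.34 (limma adjusted p = 0.00055). The other largest decreases included genes for membrane or secreted proteins, such as the glucose transporter Slc2a1 (-2.79), the secreted Tsku (-3.18), Lrig3 (-3.18) and Adm2 (-3.03). Also among them were Dhrs9 (-3.16), Lfng (-2.89), Cnnm4 (-2.84) and Pcyox1l (-2.77), whose proteins were not sorted by location here. Snhg7, Tsku, Lrig3, Adm2, Dhrs9, Lfng and Cnnm4 had migrasome means of 14.7 or lower, so their sizes are imprecise.

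**Figure D1:**
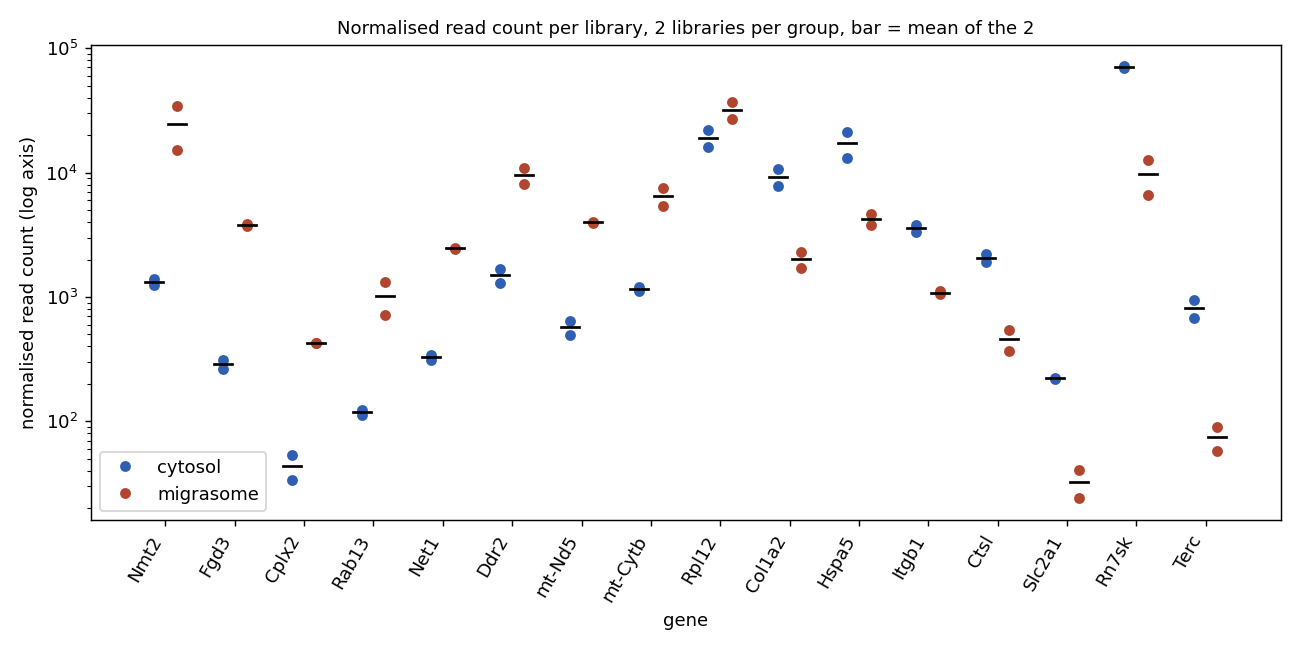
Normalised read count (log axis) of 16 genes in each of the 2 cytosol libraries (blue) and the 2 migrasome libraries (red), with a bar at the mean of each group. Nmt2 lay at 15084 and 34065 in migrasome against 1403 and 1240 in cytosol.

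mRNAs reported to collect in the protrusions of migrating fibroblasts rose together. Of the 8 tested, 7 rose and none fell, with a median log2 difference of 2.36. Ddr2, a collagen receptor, stood at 9522 ± 1952 in migrasome and 1491 ± 264 in cytosol, and the kinesin Kif1c at 7154 ± 417 and 1537 ± 41.5. Cyb5r3 (2.5 ± 0.20), Pkp4 (1.72 ± 0.19) and Trak2 (2.13) also rose. The list stood apart from the other genes by camera with its preset correlation (adjusted p = 2.1e-09), and not with an estimated one (adjusted p = 0.40 with an estimated correlation). The count adjusted over the list alone was also 7.

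Mitochondrially encoded mRNAs rose as well. All 9 tested passed, with a median log2 difference of 2.18, and 9 passed adjusted over the list alone. mt-Cytb, a subunit of respiratory complex III, stood at 6451 ± 1569 in migrasome and 1160 ± 52.0 in cytosol, and mt-Nd5 at 3975 ± 17.7 and 571 ± 103. The most abundant, mt-Co1, stood at 79596 ± 45569 and 18935 ± 7818, and its call was lost without cytosol replicate 1 (limma adjusted p = 0.085). These mRNAs, mostly mt-Co1, held 1.45% ± 0.78 of the migrasome total (0.90% and 2.01% in replicates 1 and 2) and 0.394% ± 0.128 of the cytosol total (SD, n = 2). Why some of these mRNAs had hardly any reads was not tested, so the shares hold only for the reads assigned to them. The camera adjusted p was 9.2e-09, and the adjusted p = 0.40 with an estimated correlation. The mitochondrial ribosomal RNA mt-Rnr2 stood at 165549 and 46588 in migrasome replicates 1 and 2 and at 56197 and 15156 in cytosol replicates 1 and 2, and did not pass the limma test (log2 difference 1.59, adjusted p = 0.099). Its difference was 2.5 without migrasome replicate 2 and 2.54 without cytosol replicate 1. It was 0.67 without migrasome replicate 1 and 0.64 without cytosol replicate 2. In both groups mt-Rnr2 was higher in replicate 1, an offset that same-numbered libraries shared and that widens the spread within each group. With a replicate block it passed (limma adjusted p = 4.1e-06), but the labels do not say that the numbers pair the libraries. The other mitochondrial ribosomal RNA, mt-Rnr1, was named after its values were seen and was also higher in replicate 1 of both groups. It stood at 19419 and 8040 in migrasome and at 6558 and 2315 in cytosol and passed (log2 difference 1.68, limma adjusted p = 0.033). Its difference was 1.045 without migrasome replicate 1 and 0.93 without cytosol replicate 2, and its call was lost in both. The call was also lost in other settings, such as quantile normalization (difference 1.025, limma adjusted p = 0.15). Copies of mitochondrial sequence in the nuclear genome can share reads with these genes.

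**Figure D2:**
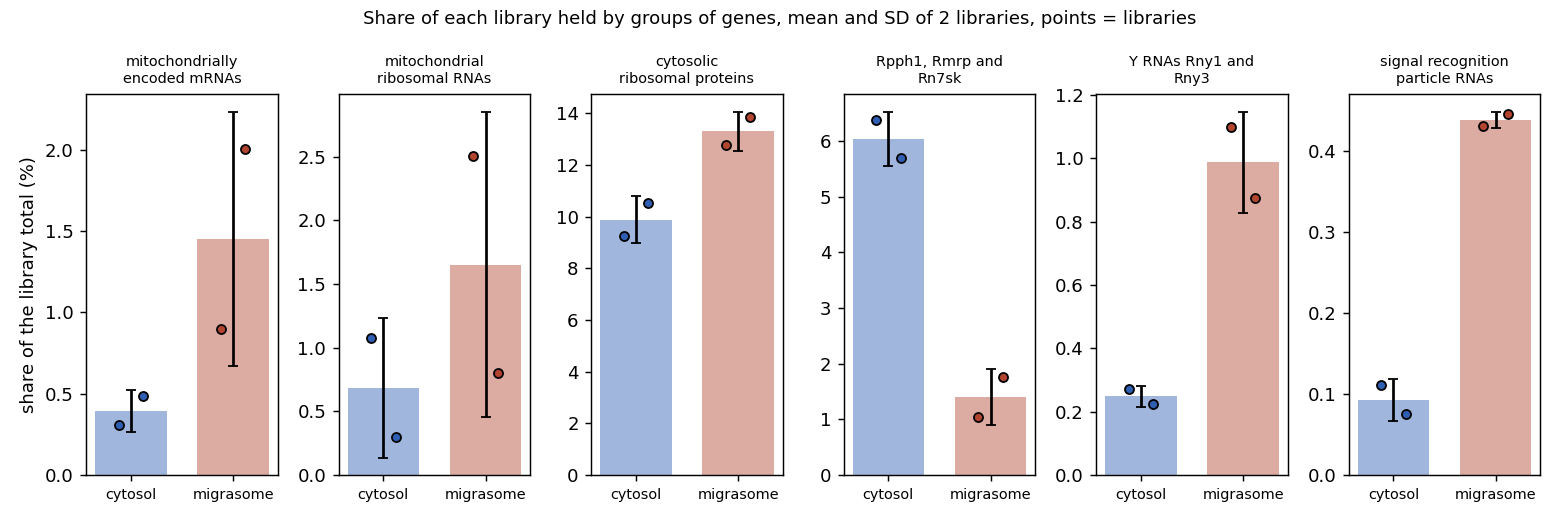
Share of each library's summed values (%) held by 6 groups of genes, as the mean (bar) and SD (line) of 2 libraries per group, with a point per library. Mitochondrially encoded mRNAs held 1.45% in migrasome and 0.394% in cytosol, and Rpph1, Rmrp and Rn7sk together 1.40% and 6.04%.

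mRNAs of the secretory pathway fell. All 27 tested genes of the secreted extracellular matrix fell, with a median log2 difference of -1.90, and 27 fell adjusted over the list alone. Col1a2, a chain of type I collagen on chromosome 6 from 4504814 to 4541544 (plus strand), fell from 9238 ± 2118 in cytosol to 2001 ± 404 in migrasome, and Fbln2 by 2.27 ± 0.23 on the log2 scale. The collagen chaperone gene Serpinh1 (-1.90 ± 0.23) and Sparc (-2.02 ± 0.22) fell too. Of the 24 endoplasmic reticulum chaperones and translocation factors, 22 fell and 2 rose, with a median of -1.89 and the same counts adjusted over the list alone. Hspa5, which encodes the chaperone BiP, fell from 17214 ± 5764 to 4210 ± 607, and Hsp90b1 (-2.03 ± 0.23), P4hb (-2.0 ± 0.22) and Canx (-1.87 ± 0.21) fell by similar amounts. The 2 that rose were Sec61b (0.70) and Sec61g (0.63), small subunits of the translocation channel that are anchored by their tails, named after their values were seen. Quantile normalization ended both calls, as did scaling to the same total per library. Both calls were lost without either cytosol library, and that of Sec61g without migrasome replicate 1 (limma adjusted p from 0.072 to 0.27). Camera gave adjusted p-values of 9.8e-16 for the matrix list and 1.8e-11 for the chaperone list. Neither held with an estimated correlation, each having an adjusted p = 0.49 with an estimated correlation.

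The mRNAs of proteins known on migrasomes or retraction fibres fell or did not pass. Of the 15 tested, 11 fell, none rose and 4 did not pass, with a median log2 difference of -1.71. The counts adjusted over the list alone were 11 and 1. Tspan4, a tetraspanin used to mark migrasomes, on chromosome 7 from 141475240 to 141493427 (plus strand), fell from 888 ± 37.5 to 265 ± 19.3, and the integrin Itgb1 from 3560 ± 312 to 1086 ± 37.4. The tetraspanin Cd63 fell by 1.94 ± 0.20 on the log2 scale. Genes for other membrane proteins fell widely too, the Tmem genes in 75 of 136 cases with 2 rising (median -1.10). The fall is thus not shown to be particular to migrasome proteins. The camera adjusted p was 3.5e-06, and the adjusted p = 0.49 with an estimated correlation.

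In the lysosome and autophagy list 18 of 31 fell, none rose and 13 did not pass (median -1.52, camera adjusted p = 0.00021, adjusted p = 0.50 with an estimated correlation). Adjusted over the list alone, 18 fell and 4 rose. Ctsl, a lysosomal protease (-2.20 ± 0.23), Lamp1 (-1.61 ± 0.21) and Psap (-1.98 ± 0.21) fell, and the autophagy receptor gene Sqstm1 stood at 3859 ± 775 and 2564 ± 482 without passing. In the glycolysis list 10 of 17 rose and 1 fell (median 0.68, camera adjusted p = 0.00027, adjusted p = 0.50 with an estimated correlation), with 11 rising and 1 falling adjusted over the list alone. The one that fell was the membrane transporter Slc2a1, whereas the enzyme genes Pkm (1.19 ± 0.26), Pgk1 (1.06) and Eno1 (0.82 ± 0.22) rose. In the cholesterol synthesis list 8 of 19 fell and 1 rose (median -0.69, camera adjusted p = 0.032, adjusted p = 0.50 with an estimated correlation), with 10 and 1 adjusted over the list alone. Cyp51 (-1.62 ± 0.29) and Insig1 (-0.76) fell, Fdps rose (0.80 ± 0.24), and Hmgcs1 stood at 855 ± 7.62 in migrasome and 937 ± 18.7 in cytosol without passing. Without cytosol replicate 1 the median of the list was -0.40. The cholesterol call was lost with eBayes without a trend (adjusted p = 0.067) and without migrasome replicate 2 (adjusted p = 0.056). Among fibroblast markers 5 of 9 fell and 1 rose, and the list did not pass (camera adjusted p = 0.13). It did pass with a minimum mean of 50 (adjusted p = 0.043), quantile normalization (0.018), edgeR (0.025) and without cytosol replicate 2 (0.00078). Adjusted over the list alone the counts that fell and rose were 5 and 1. Collagen I genes Col1a1 (-1.97 ± 0.22) and Col1a2 (-2.20 ± 0.25) fell, the intermediate filament gene Vim rose (0.94), and S100a4 stood at 33718 ± 5382 and 23663 ± 1099 without passing. Quantile normalization ended the calls of Pkm, Eno1, Fdps and Vim, and scaling to the same total per library those of Eno1 and Fdps. The calls of Pkm, Eno1, Fdps, Insig1 and Vim were lost without either cytosol library, that of Pgk1 without cytosol replicate 1, and those of Fdps and Insig1 also without migrasome replicate 1 (limma adjusted p from 0.053 to 0.33).

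**Figure D3:**
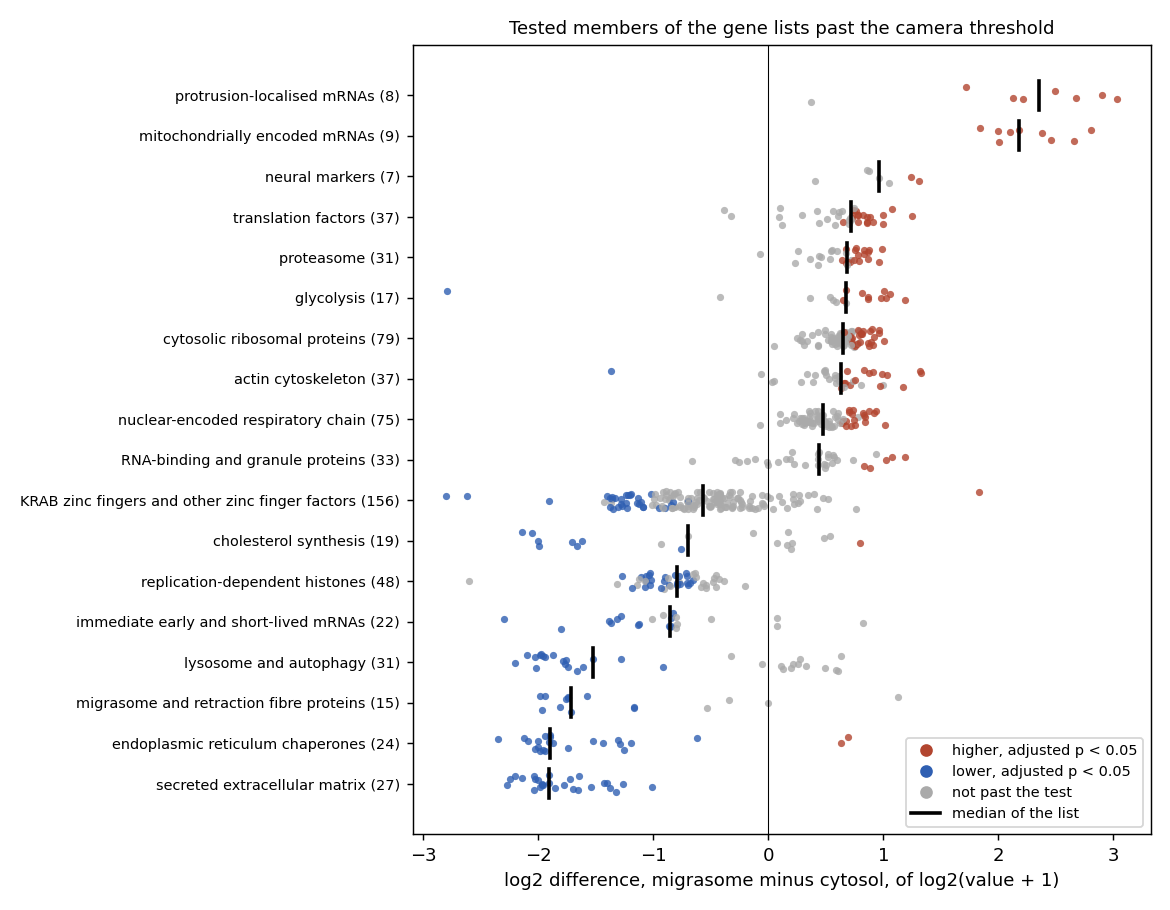
Log2 difference, migrasome minus cytosol, of every tested member (points) of the 18 gene lists past the camera threshold with its preset correlation, with a black line at each list's median and the number of tested members in brackets. Red and blue points passed the limma test as higher and lower, and grey points did not pass. All 27 matrix genes lay below 0, and all 9 mitochondrially encoded mRNAs above it.

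mRNAs of ribosomal proteins, translation factors, the proteasome and the nuclear-encoded respiratory chain were higher by smaller amounts. Of 79 cytosolic ribosomal protein genes 25 rose and none fell, with 79 positive differences and a median of 0.65. When adjusted over the list alone, 50 rose. Rps3 rose by 0.96 ± 0.27, and Rplp0 stood at 37237 ± 1908 in migrasome and 23738 ± 2373 in cytosol without passing (limma adjusted p = 0.10). These genes held 13.3% ± 0.77 of the migrasome total and 9.87% ± 0.90 of the cytosol total. The camera adjusted p was 1.3e-13, the adjusted p = 0.49 with an estimated correlation, and with quantile normalization the median fell to 0.03 (adjusted p = 0.99). Of 37 translation factors 18 rose and none fell (median 0.72), led in abundance by Eef1a1 at 109542 ± 10897 and 51719 ± 2089. Adjusted over the list alone 26 rose, the camera adjusted p was 1.6e-08, and the adjusted p = 0.50 with an estimated correlation. With quantile normalization the median was 0.31 (adjusted p = 0.072). Of 31 proteasome subunits 17 rose (median 0.69, camera adjusted p = 1.3e-08, adjusted p = 0.50 with an estimated correlation), such as Psmd2 (0.97 ± 0.23) and Psmc3 (0.87 ± 0.22), and 22 adjusted over the list alone. Of 75 nuclear-encoded respiratory chain genes 19 rose (median 0.48, camera adjusted p = 6.1e-11, adjusted p = 0.50 with an estimated correlation), such as Atp5b (1.01 ± 0.26) and Atp5a1 (0.92 ± 0.22), and 20 adjusted over the list alone. Ribosomal protein genes have many near-identical pseudogenes, so their single values are uncertain. With quantile normalization, and all 4 libraries kept, the calls of Rps3, Psmd2, Psmc3, Atp5b and Atp5a1 were lost. The calls of Rps3, Eef1a1, Psmd2, Psmc3, Atp5b and Atp5a1 were each lost without either cytosol library (limma adjusted p from 0.061 to 0.36).

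In the actin cytoskeleton list 15 of 37 rose and 1 fell (median 0.63, camera adjusted p = 4.6e-08, adjusted p = 0.49 with an estimated correlation), with 24 and 1 adjusted over the list alone. Myh9, a non-muscle myosin heavy chain, rose by 1.33 ± 0.30, Actg1 by 1.32 ± 0.32 and Tpm4 by 1.03 ± 0.25. Vcl, which encodes vinculin, was the one that fell (-1.37). Actb stood at 102589 ± 14040 and 52052 ± 13023 without passing (limma adjusted p = 0.056). Of 33 RNA-binding and granule protein genes 5 rose and none fell (median 0.44, camera adjusted p = 0.00063, adjusted p = 0.49 with an estimated correlation), 5 also adjusted over the list alone, among them Hnrnpk (0.88 ± 0.23). That list did not pass with quantile normalization (adjusted p = 0.16), and its median without migrasome replicate 1 was 0.23. Quantile normalization also ended the calls of Myh9, Actg1, Tpm4 and Hnrnpk. The calls of Tpm4 and Hnrnpk were lost without either cytosol library, that of Actg1 without cytosol replicate 1 and that of Myh9 without cytosol replicate 2 (limma adjusted p from 0.051 to 0.21).

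Replication-dependent histone genes, whose mRNAs end in a stem-loop without a poly(A) tail, fell in 25 of 48 cases with none rising (median -0.79, camera adjusted p = 2.1e-09, adjusted p = 0.49 with an estimated correlation). Adjusted over the list alone, 40 fell. Hist1h4c fell by 0.79 ± 0.21 and Hist1h4f by 0.93 ± 0.20 on the log2 scale. Histone genes are near-identical copies, and their single values are uncertain. Of 22 immediate early and short-lived mRNAs 13 fell and none rose (median -0.86, camera adjusted p = 4.2e-05, adjusted p = 0.51 with an estimated correlation), with 16 adjusted over the list alone. Jun (-1.12 ± 0.24), Myc (-1.13), Klf6 (-0.83 ± 0.21) and the secreted Cyr61 (-1.80) were among them. Of 156 zinc finger factors 32 fell and 1 rose (median -0.56, camera adjusted p = 1.1e-05, adjusted p = 0.55 with an estimated correlation), with 22 and 1 adjusted over the list alone. Without migrasome replicate 1 their median was -0.31. Of all 10860 tested genes 1919 fell, a share near that of the zinc finger factors. Leaving out either cytosol library ended the calls of Hist1h4c, Hist1h4f and Klf6, and leaving out cytosol replicate 2 that of Jun (limma adjusted p from 0.057 to 0.23).

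Abundant short non-coding RNAs went both ways, and the list did not pass (camera adjusted p = 0.30). Of 16 tested, 5 rose and 10 fell, with 6 and 10 adjusted over the list alone. The Y RNA Rny1 stood at 47852 ± 8758 in migrasome and 10833 ± 680 in cytosol, and Rny3 rose by 2.61. Rn7s1, an RNA of the signal recognition particle with near-identical copies, stood at 8904 ± 1752 and 1168 ± 300. The catalytic RNAs Rpph1 (-1.77 ± 0.39) and Rmrp (-1.53 ± 0.30) of ribonucleases P and MRP fell. Rpph1, Rmrp and Rn7sk together held 6.04% ± 0.49 of the cytosol total and 1.40% ± 0.51 of the migrasome total. The nuclear-retained long non-coding RNAs were present in the cytosol libraries, Malat1 at 8064 ± 3494 and Tug1 at 1134 ± 17.7. In migrasome they stood at 4492 ± 863 for Malat1, which did not pass (limma adjusted p = 0.084), and 584 ± 55.7 for Tug1, which fell (limma adjusted p = 0.0074). Of 8 tested in that list 1 rose and 2 fell, with 2 and 3 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.30). Leaving out either cytosol library ended the call of Rpph1, cytosol replicate 1 that of Rmrp and cytosol replicate 2 that of Tug1 (limma adjusted p from 0.054 to 0.11).

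Other lists did not pass by camera. The lists were cell division (9 of 33 rose and 1 fell, adjusted p = 0.081), extracellular vesicle biogenesis (3 of 26 rose and 2 fell, adjusted p = 0.17), splicing factors (1 of 30 rose and 3 fell, adjusted p = 0.20), snoRNA host genes (5 of 17 fell, among them Snhg7 and Snhg20 at -2.45, adjusted p = 0.17) interferon response (1 of 9 rose and 2 fell, adjusted p = 0.80) and the PI3K pathway (1 of 18 rose and 1 fell, adjusted p = 0.75). Cell division passed without migrasome replicate 2 (adjusted p = 0.048) and without cytosol replicate 2 (0.020), splicing factors without migrasome replicate 2 (0.032), and snoRNA host genes with no filter (0.048). Adjusted over the list alone, the counts that rose and fell were 11 and 2, 3 and 2, 0 and 0, 0 and 5, 2 and 2, and 0 and 0. Of the markers of other cell types, neural markers passed by camera (median 0.97, adjusted p = 0.012, adjusted p = 0.49 with an estimated correlation) at low levels, with 2 of 7 rising, 2 adjusted over the list alone, and Map2 at 31.4 ± 1.6 and 12.2 ± 3.05. The Map2 call was lost without migrasome replicate 1 or either cytosol library (limma adjusted p from 0.056 to 0.27). Epithelial, leukocyte, endothelial and hepatocyte and erythroid markers each had fewer than 5 tested members, the most abundant being Coro1a at 38.3 in cytosol.

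The replicates differed by an SD of 0.58 in log2 between the migrasome libraries and 0.38 between the cytosol libraries, over the 10860 tested genes. Across genes, Pearson's r of the log2 values was 0.971 within migrasome, 0.984 within cytosol and between 0.902 and 0.935 across groups. Genes are not independent replicates, so no p is given.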

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

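The thinning to equal depth was chosen after the data were seen, and the other alternatives before. Against 2862 calls (943 higher, 32.9%), the settings within 1.5 times included edgeR (1071 higher and 2064 lower), DESeq2 (1140 and 1599), thinned reads (1009 and 1760), exon length correction (1042 and 1937) and GC correction (929 and 1889). The total was 1741 with no filter, where the genes tested rose to 19077, with 393 calls higher (22.6%). Genes higher numbered 322 with the same total per library (11.3%, median of all genes moved to -0.273), 473 with that total counted without mitochondrial and ribosomal protein genes (17.7%, -0.184) and 483 with eBayes without trend (22.4%), against 46.0% of calls higher with quantile normalization (median 0.112). A fold minimum of 2, a stricter test by construction, left 102 calls (29 higher and 73 lower). Leaving out 1 library gave 1414 to 4885 calls, 231 to 2085 higher and 1147 to 2800 lower, the lowest totals without cytosol replicates 2 (1414) and 1 (1433) and the highest without migrasome replicate 2. A lone library is there assumed to vary like the other group. The replicate numbers are not said to pair the libraries, and deviations of same-numbered libraries correlated at 0.226 across genes. With the replicate block 4423 genes passed, 1802 of them higher. With it the neural marker list no longer passed (adjusted p = 0.050) and the fibroblast list did (0.0067), as did mt-Rnr2 (limma adjusted p = 4.1e-06). Of 89 named genes past the threshold, 31 lost their call in some setting, 30 of them with 1 library left out, and none of them turned. The SD between cytosol libraries was 0.6185 over genes with any read.

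Directions turned for results that were not past their tests. With the same total per library these were the medians of PI3K pathway (-0.2348), cell division (-0.2353), vesicle biogenesis (-0.09849) and splicing (-0.072). With quantile normalization they were Rpl12 (-0.01242), S100a4 (-0.07655), PI3K pathway (-0.01069), cell division (-0.06363) and splicing (-0.008863). With the total without mitochondrial and ribosomal protein genes they were PI3K pathway (-0.1454), cell division (-0.1443) and vesicle biogenesis (-0.007704). Leaving out 1 library, the PI3K pathway median ranged from -0.1129 (without migrasome replicate 2) to 0.1526, turning also without cytosol replicate 2 (-0.02438), and the splicing median from -0.002763 (without migrasome replicate 1) to 0.3783. Also turned were fibroblast markers with no filter (0.5024). Except for the changes of filter and library number, the cause was not tested. Low genes varied more, the SD between migrasome libraries being 0.716 for mean values of 10 to 100 and 0.435 above 1000. Whether depth accounts for that was not tested.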

Other observations

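Families grouped by symbol, and the tests of this part apart from the first comparison of Slc25 with other Slc genes, were chosen after the results were seen. The enrichment of these families was not tested, and of all 10860 genes 1919 fell. Of 133 Slc transporter genes other than Slc25, 87 fell and 1 rose by limma (median log2 difference -1.36), such as the amino acid transporters Slc7a5 (-2.15) and Slc38a2 (-1.6). Of 36 Slc25 genes, which encode carriers of the mitochondrial inner membrane, 3 fell and 1 rose, with a median of -0.16 that turned positive with quantile normalization. The one that rose was Slc25a5 (0.90). Its call was lost without either cytosol library, with quantile normalization and with the same total per library. Tmem genes fell in 75 of 136 cases, rose in 2 and did not pass in 59 (median -1.10), Alg glycosylation enzymes fell in 9 of 12 (-1.47) and Cd surface antigens in 14 of 18 (-1.61), 5 of which are also in a fixed list. These 4 families other than Slc25 stayed negative under all scalings run. Of 43 Rab GTPase genes, 4 of them in a fixed list, 2 rose and none fell, and of 77 mitochondrial ribosomal protein genes 2 rose and none fell.

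Small RNAs split by class. Of 42 snoRNA genes 25 fell and none rose (median -1.57), of 11 scaRNA genes 10 fell (-1.91), and of 12 snRNA genes 10 fell (-1.67), among them Snora73a (-1.38), Scarna2 (-1.86) and the minor spliceosome RNA Rnu12 (-1.45). All 5 Y and signal recognition particle RNAs rose (median 2.56), as did all 4 tested mitochondrial tRNAs (2.13). Of 175 processed pseudogenes 39 rose and none fell, which can include reads of their parent genes. The signs of these class medians held under all scalings run.

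The fall of secretory pathway mRNAs kept its size under the technical corrections. The median of the matrix and chaperone genes together was -1.76 after GC correction and -1.88 after exon length correction, which argues against each as the whole cause. A scaling factor per library moves all genes alike and cannot set these genes apart from the rest. Their distance from the median of all genes was -1.54 or lower in each of the 4 pairs of a migrasome and a cytosol library. That distance restates the fall of lists already seen to fall, and is not a separate test of scaling. A candidate explanation is that mRNAs translated at the endoplasmic reticulum stay with it: Slc genes other than Slc25 had a median -1.19 relative to Slc25 genes. That comparison was written on the premise that the families are equally hydrophobic, which these data contradict, since 94.7% and 22.2% of them code a 19-residue window with mean Kyte-Doolittle hydropathy of at least 1.9, but among genes with such a window the difference was -1.47, on only 8 Slc25 genes. Outside the fixed lists, 1008 of 1874 coding genes with such a window fell against 647 of 7505 without it, and the difference of medians was -0.928 or lower in each of the 4 pairs, with the bound set after the trend was seen.

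Nuclear small RNAs are here the snoRNA, scaRNA and snRNA genes together with Rpph1, Rmrp, Rn7sk and Terc. The fall of these RNAs, in 49 of 69 tested, may come from nuclear RNA in the cytosol libraries, which the nuclear-retained long non-coding RNAs left open. Their median log2 difference was -0.67 (quartiles -0.80 and -0.15), with 2 of 8 lower and 1 higher, and -0.33 without cytosol replicate 1. A loss of short RNAs by length from the migrasome libraries was looked for in 10 tested non-coding RNAs outside the nuclear classes. Their exon lengths were up to 191 bases, the upper quartile of the nuclear small RNAs. They had a median of 2.09 (quartiles 1.87 and 2.23), with 9 higher and none lower. The 9 include the mitochondrial tRNAs, Rny1, Rny3 and Mir1983, already seen to rise, so that median is not a separate test of such a loss. It shows only that short length alone did not make an RNA lower in migrasome. Of all 30 tested non-coding RNAs outside the nuclear classes and under 500 bases, 17 were higher and 7, of 290 to 338 bases, lower. Some of the 7 were annotated as ribozymes, as is Rpph1. The others were unnamed models of the broad class misc_RNA, which also holds Rn7sk and Rn7s1. The 7 may thus include nuclear RNAs that the classes missed, and do not by themselves show a loss outside those classes. A loss that spared some short RNAs, or that their enrichment masked, stays open. Whether migrasomes exclude nuclear RNA beyond what any sample without nuclei would show cannot be read from these libraries.

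Migrasome replicate 2 lay nearer to the cytosol libraries (r of 0.930 and 0.935) than replicate 1 (0.907 and 0.902), and its 0.989 times the reads of replicate 1 argue against sequencing depth as the cause. If cell-body RNA had been carried into replicate 2, the share needed to turn replicate 1 into it had a median of 10.5% for matrix genes and 7.0% for endoplasmic reticulum chaperones but -5.14% for nuclear small RNAs (quartiles -21.4% and 6.28%). That median met the bound first set against carry-over, a median at or below 0, but the further need for both quartiles below 0 was set after this value was seen, and with quartiles that span 0 carry-over is left open. The mitochondrially encoded mRNAs, which carry-over would lower, had a median log2 difference of 0.173 between replicates 2 and 1, inside the range that decides nothing. No biological explanation of this difference was tested, as the labels give none.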
